A study of Homo sapiens with 4 samples.

How the data were processed

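The series compared cultured pancreatic stellate cells, the fibroblast-like cells of the pancreatic stroma, with and without the cytokines tumour necrosis factor alpha (TNFa) and interferon gamma (IFNg). Per the labels' protocols, 100000 cells were embedded in 50 µl Matrigel domes and kept in medium with 5% serum, and the treatment lasted 6 hr. RNA was pooled from 4 wells for each extraction, libraries were made from 4 µg of total RNA with 12 cycles of PCR, and single-end reads of 76 bp were sequenced. The cytokine doses are not given in the sources used here. There were 4 samples, 2 control and 2 treated, numbered within each group by the labels. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The organism label reads human, whereas the design text names mouse cells, the submitters' processing notes name mouse builds and the table holds mouse gene symbols; the cells are treated here as mouse cells. The molecule label reads polyA RNA, whereas the named library kit is one for total RNA, and the values do not settle which was used.

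The deposited table holds a signal of normalized counts per gene, 1 column per library, made by the authors with DESeq2, per the name of the table. The submitters' processing notes list STAR 2.5.2b-1, featureCounts 1.4.6 and DESeq2, with the builds GRCm38 and mm10 and no settings. The gene annotation, the handling of reads with several matches and the strand setting of the counting are not given in the sources used here, so values of close paralogs, overlapping genes and antisense genes are uncertain. No mouse annotation was used here, so genes carry the symbols of the table and no coordinates. The table has 25229 rows, of which 19150 hold a value above 0. In 26 rows the gene name had been turned into a calendar date by a spreadsheet program; these rows stayed in the tests without a name, took between 0.232% and 0.240% of the reads of a library and included 21 tested rows. Each value column shows its group and no replicate number, so columns are called the first and second library of a group, in the order of the table, and are not paired. The number of value columns without a group was 0.

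Each column is a set of whole multiples of 1 step, the worth of 1 read. Division by that step gave whole reads for 100% of the values above 0 in every library, within a tolerance of 0.01 reads. The recovered depths were 48424779 and 42021234 reads in the control libraries and 46570663 and 50995817 reads in the treated libraries, and size factors recomputed from them with DESeq2 matched the steps (1.25 and 1.10 for control, 0.813 and 0.901 for treated). At this depth 1 read was worth between 0.798 and 1.23 normalized counts. Where a group held no read, a fold bound was computed against a floor of 3 reads over the group; where it held 1 to 3 reads, the ratio of reads is given with an exact 95% interval. Intervals and floors cover counting error only, since reads after PCR are not independent molecules.

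Genes entered the tests when their mean over the 4 libraries was at least 10 normalized counts, which left 14128 genes. The main test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 changes are treated minus control on that scale, which understates the change of low genes. Values are means ± SD with n = 2 libraries in each group, and each adjusted p of a gene below comes from that limma fit. Gene lists, 32 in number, were written before the data were examined, and those with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists. Camera with an estimated correlation, which works with only the 2 residual degrees of freedom (df) of these libraries and so has little power, and fry stood beside it. Members of each list were also counted with p adjusted over the list alone. The 16 genes held by 2 lists count in both.

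Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes whose treated values both lay on the same side of both control values, passing over predicted genes without a proper name. It adds up to 4 measured members of each list with the smallest adjusted p, every measured chemokine gene, and Cxcl12, Cxcl9, Cxcl10, Cxcl16, Il6, Acta2 and Col1a1. Some genes taken by this rule are not reported here by name; they stay in the counts and list values. Any other gene named in the text was chosen after its values were seen, which holds for the gene families in the last part and for genes given to describe the libraries.

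The procedure was tested on simulated data drawn from the control means and the estimated spread, with 200 genes changed between the groups, and 13766 simulated genes, changed or not, passed the filter. At changes of 1.5, 2, 4 and 8-fold, the limma step called 59.2%, 80.0%, 100% and 100% of the changed genes, and 4.05% of its calls were false (7 of 173). The simulation changed few genes, up and down alike, and divided by the true size factors, so it holds no error of scaling. In the data most genes were called, so this false rate does not carry over to them. Alternatives planned before the data were examined were pseudocounts of 0.5 and 10, no filter, a filter of 50, each library left out, median centring, quantile normalization, TMM factors, limma without a trend, the quasi-likelihood test of edgeR (version 4.0.16) and the Wald test of DESeq2 (version 1.42.0) on the recovered reads, and a 2-fold minimum. Scaling by the library total, TMM factors for lists, chemokines and named genes, median centring for lists and a fit with columns paired by their order were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.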

Results

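Gene expression was measured by RNA sequencing in the pancreatic stellate cell line PSC4, cultured in Matrigel domes, after 6 hr with TNFa and IFNg or without them. There were 2 control and 2 treated libraries, with 48424779 and 42021234 recovered reads in the control libraries and 46570663 and 50995817 in the treated ones. Across the 14128 genes tested, log2 values of the 2 control libraries correlated with a Pearson r of 0.995 and those of the 2 treated libraries with 0.995, against 0.871 to 0.881 between groups; genes are not independent replicates. Libraries of a group differed by far more than counting noise, with a chi-square of 15.6 per gene for the control pair and 20.4 for the treated pair where 1 would be counting noise alone, so no library was a copy of another.

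The comparison asks what TNFa and IFNg together do to the transcripts of these cells, with the chemokines that the series title names at its centre. Most tested genes were called different after 6 hr of treatment, a difference beyond the spread between these libraries, which may be technical. Chemokines such as Cxcl9, antigen presentation genes, guanylate-binding proteins and NF-kB genes rose together, while Cxcl12, which held most chemokine counts of the control cells, fell. Of the 14128 genes, 5478 were higher and 5124 lower after treatment, and 3526 did not pass the test. At least a 2-fold change was seen in 2154 of the higher and 2247 of the lower genes. Rises reached further than falls: 309 genes rose at least 16-fold and 44 fell at least 16-fold.

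The 10 largest called rises included 2 ligands of the chemokine receptor Cxcr3. Cxcl9 went from 12.1 ± 3.5 to 919994 ± 143538 normalized counts (SD, n = 2), a log2 change of 16.12 with a standard error (SE) of 0.19 and an adjusted p of 3.97e-07 in limma. Cxcl11 rose from 3.01 ± 0.874 to 13334 ± 422 (log2 change 11.72, SE 0.17). The ubiquitin-like modifier gene Ubd rose by a log2 change of 15.27 (SE 0.66), resting on 4 control reads, and by 14.17 and 16.38 without the first and the second control library. Nos2, which encodes the inducible nitric oxide synthase, rose from 3.47 ± 1.52 to 77681 ± 10049 (log2 change 14.12, SE 0.24, adjusted p = 8.57e-07). The acute phase gene Saa3 (11.81), Gbp4 (11.07), the itaconate-producing enzyme gene Acod1 (10.51), the perforin family gene Mpeg1 (9.93) and Calhm6 (9.89) followed on the log2 scale, with Calhm6 at 9.23 and 10.54 without the first and the second control library. Cd40, the receptor for the T cell ligand CD154, had 2 reads in the control group, and its ratio of reads was 3535-fold with a 95% interval of 978 to 29195. Control reads were also few for Cxcl11 (7), Nos2 (8), Saa3 (13), Gbp4 (11), Acod1 (4) and Calhm6 (8). Counting error limits the folds of these genes, and the SE may understate it.

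The 10 largest called falls were smaller. Dkk2, a secreted modulator of Wnt signalling, went from 7598 ± 3205 to 79.6 ± 23.2 normalized counts (log2 change -6.52, SE 0.32, adjusted p = 1.67e-05). Angpt2, which encodes a ligand of the receptor Tek, fell from 3183 ± 36.2 to 65.8 ± 4.25 (log2 change -5.58, SE 0.09). Mrvi1 (-6.15), the iron exporter gene Slc40a1 (-5.44), the natriuretic peptide clearance receptor gene Npr3 (-4.97), Galnt15 (-4.89) and Id4 (-4.81) fell as well. Treated reads were few for Mrvi1 (14), Slc40a1 (13) and Galnt15 (20), so counting error limits their folds. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, had 1 read in the treated group, and its ratio was 199-fold lower with a 95% interval of 35.5 to 7906. Prr9 and Ankef1 had no read after treatment and were at least 80.1-fold and 15.5-fold lower, against the floor over the group.

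**Figure D1:**
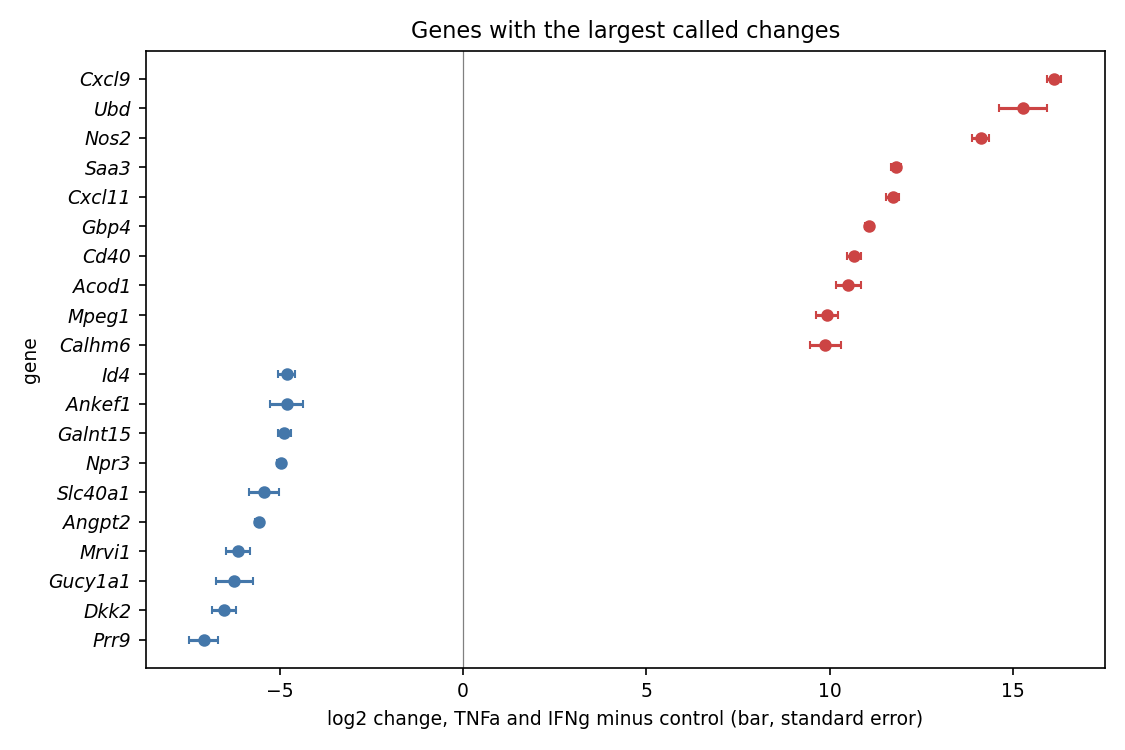
Log2 change, treated minus control, of the 10 genes with the largest rise and the 10 with the largest fall among called genes; points are limma estimates from 2 libraries in each group and bars are standard errors. Rises run from 9.89 for Calhm6 to 16.12 for Cxcl9, and falls from -4.81 for Id4 to -7.08 for Prr9, whose treated libraries held no read. For genes with few reads in a group the bars may understate counting error.

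All 10602 called genes had both treated values on 1 side of both control values, which 88.6% of tested genes showed and chance gives for 33.3%. The sum of normalized counts was 1.48 times higher in the treated libraries, so the split between higher and lower calls depends on the scaling: 51.7% of calls were higher with the deposited size factors, while scaling by the library total, added after the data were seen, moved the median of all genes to a log2 value of -0.56 and gave 2624 higher and 9054 lower genes. Quantile normalization moved that median to -0.14 and gave 4458 higher and 6101 lower genes.

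Chemokine transcripts changed almost without exception. Of 27 measured chemokine genes, 24 rose, 2 fell and 1 did not pass the test, and the numbers adjusted over the list alone were 24 and 2. At least a 10-fold rise was seen in 21 of them. Cxcl10, another Cxcr3 ligand, rose from 1542 ± 780 to 489377 ± 17676 normalized counts (log2 change 8.41, SE 0.32, adjusted p = 7.31e-06). The monocyte attractant Ccl2 rose 103-fold to 190601 ± 13940, Ccl5 rose 160-fold to 121327 ± 1843, Ccl7 rose 55.4-fold, and the membrane-bound chemokines Cxcl16 and Cx3cl1 rose 14.7-fold and 10.7-fold. Ccl19, a ligand of Ccr7 on naive T cells and mature dendritic cells, and Ccl1 had no read in the controls and were at least 155-fold and 175-fold higher.

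Cxcl12, which attracts Cxcr4-bearing cells and is a well-known product of stromal fibroblasts, fell from 203245 ± 38214 to 26006 ± 2629 normalized counts (log2 change -2.96, SE 0.14, adjusted p = 1.56e-05). It made up 93.7% of all chemokine counts in the controls and 1.34% after treatment. Chemokine genes together took 0.563% of normalized counts in the controls and 3.40% after treatment. Ccl28 fell 5.54-fold, Ccl25 rose 2.04-fold, and Ccl27a was at 152 ± 1.83 in the controls and 117 ± 31.8 after treatment (adjusted p = 0.134), a fall that passed the test without the second treated library (log2 change -0.68, adjusted p = 0.0206) and under library total scaling (-0.96, adjusted p = 0.00656). All 12 measured chemokines that attract T cells and NK cells rose, with a median log2 change of 5.78 (camera adjusted p = 1.34e-05; adjusted p = 0.334 with an estimated correlation). All 9 measured chemokines that attract neutrophils and monocytes rose too, with a median of 6.04 (camera adjusted p = 7.69e-05; adjusted p = 0.390 with an estimated correlation).

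**Figure D2:**
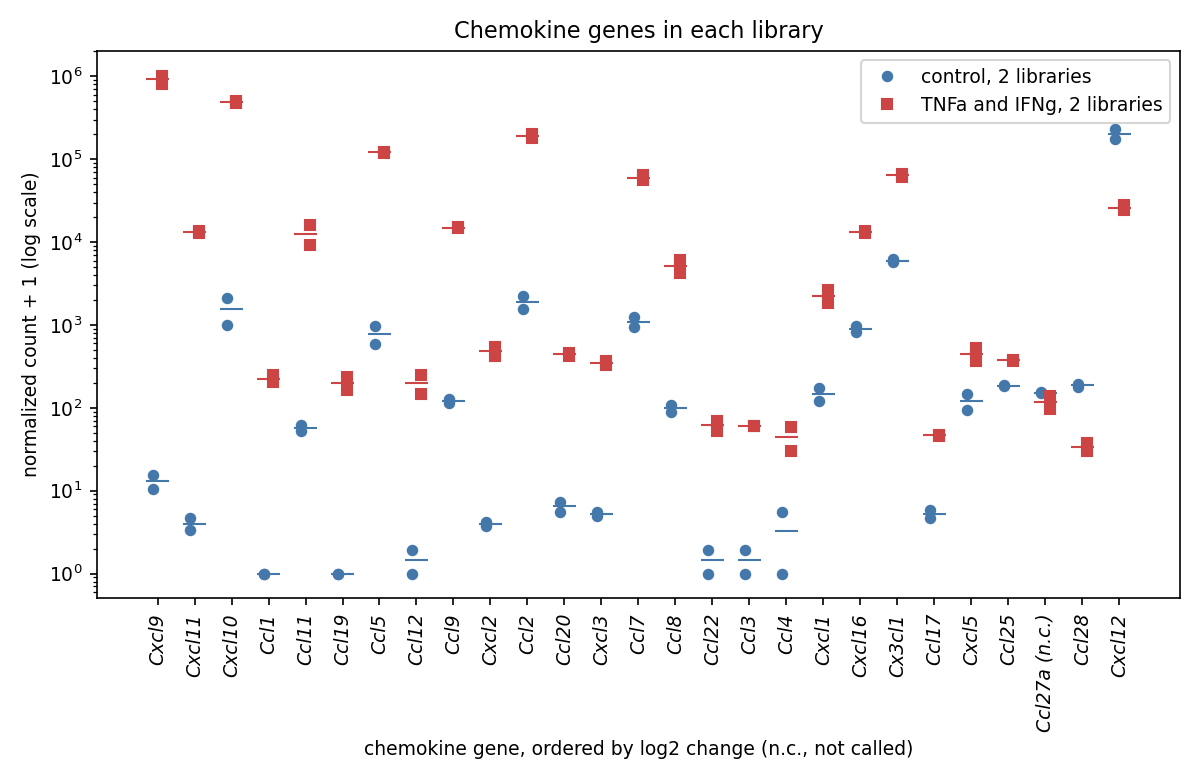
Normalized count plus 1, on a log scale, of the 27 measured chemokine genes in each library; circles are the 2 control and squares the 2 treated libraries, and lines are group means. Cxcl9 and Cxcl10 reach 919994 and 489377 after treatment on average, while Cxcl12 falls from 203245 to 26006.

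All 20 regulators of IFNg signalling rose, with a median log2 change of 2.64, and the 18 guanylate-binding proteins and immunity-related GTPases rose by a median of 7.59. The transcription factor genes Batf2 and Irf1 rose 864-fold and 46.6-fold, and the feedback inhibitor gene Socs1 rose 37.0-fold. Gbp2 went from 2292 ± 748 to 918992 ± 70891 normalized counts. The 27 antiviral genes rose by a median of 3.61, among them Samhd1 (24.7-fold) and Ifit2 (6.85-fold). Camera gave adjusted p of 1.21e-07, 8.10e-08 and 4.98e-07 for these 3 lists, and adjusted p of 0.334, 0.390 and 0.515 with an estimated correlation. The control libraries were not alike in these genes: 25 of the 27 antiviral genes were higher in the second control library than in the first, by a median log2 difference of 1.12, and the guanylate-binding list differed by 0.84. Reads of near-identical family members cannot be assigned with certainty here.

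Antigen presentation genes of both classes rose. For MHC class I, 22 of 22 measured genes rose by a median log2 change of 3.22, and 20 rose and 2 fell under quantile normalization; Nlrc5, the activator of class I genes, rose 33.1-fold, the immunoproteasome subunit gene Psmb9 38.5-fold and the peptide transporter gene Tap2 14.4-fold. For MHC class II, 10 of 10 rose by a median of 3.74. Ciita, the master regulator of class II genes, went from 17.9 ± 0.419 to 5924 ± 1889, the invariant chain gene Cd74 from 93.7 ± 33.1 to 9424 ± 1818, and H2-Aa from no read to 936 ± 367, at least 724-fold higher. The adjusted p from camera was 1.76e-09 for class I and 4.19e-04 for class II, with adjusted p of 0.334 and 0.390 with an estimated correlation.

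All 21 measured NF-kB pathway and feedback genes rose, by a median log2 change of 2.88, including Tnfaip2 (38.4-fold), the inhibitor gene Nfkbia (11.2-fold) and the subunit gene Nfkb1 (7.37-fold). Of 13 receptors and adaptors for TNF and interferons, 12 rose and 1 fell, 9 and 1 under library total scaling; Ifnar2 rose 4.77-fold and Ripk1 3.35-fold. Among 17 adhesion and immune checkpoint genes, 15 rose and 2 fell. Vcam1 went from 3181 ± 185 to 289608 ± 17153 normalized counts, Icam1 rose 673-fold, and Cd274, which encodes the checkpoint ligand PD-L1, rose 133-fold. Camera gave adjusted p of 1.76e-09, 3.10e-04 and 7.69e-05 for the 3 lists, and adjusted p of 0.334, 0.390 and 0.334 with an estimated correlation.

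Of 24 measured cytokine and growth factor genes, 18 rose, 3 fell and 3 did not pass the test. Il6 rose from 19.9 ± 1.20 to 837 ± 288 (log2 change 5.28, SE 0.25, adjusted p = 1.47e-05), the T and NK cell growth factor gene Il15 50.1-fold, Lif 29.3-fold and the macrophage growth factor gene Csf1 6.47-fold. Cell death genes split 18 higher, 2 lower and 2 not passing, 18 higher and 4 lower under quantile normalization and 14 higher and 4 lower under library total scaling (median 0.78), with Fas, the death receptor gene, up 35.4-fold and Casp4 up 27.4-fold. Of 15 nitric oxide, tryptophan and redox genes, 12 rose and 3 fell, with Sod2 up 39.9-fold and Wars up 37.6-fold. Of 11 complement genes 9 rose and 2 did not pass, with C3 up 167-fold and Cfb up 192-fold. The median log2 changes of these 4 lists were 2.29, 1.35, 5.23 and 3.08. Their camera adjusted p were 9.10e-04, 7.69e-05, 2.33e-04 and 7.69e-05, against adjusted p of 0.334, 0.334, 0.334 and 0.390 with an estimated correlation.

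Stromal genes moved in both directions. Among 16 contractile and myofibroblast genes, 3 rose, 6 fell and 7 did not pass the test. Tgfbi rose 2.28-fold, whereas the smooth muscle genes Lmod1 and Cnn1 fell 13.5-fold and 3.59-fold. Acta2, which encodes alpha smooth muscle actin, was at 13138 ± 5765 in the controls and 21184 ± 7860 after treatment (log2 change 0.71, SE 0.36, adjusted p = 0.119); without the first control library the change was 1.17 and passed the test (adjusted p = 0.00348), in a fit whose prior df was 7.0 against 3.75 with all libraries, which lowers p. The first library of each group was the higher one for Acta2. A limma fit paired by column order, a pairing that no label states, called Acta2 higher at the same log2 change of 0.71 (adjusted p = 1.19e-05), so its rise stays open. Of 24 collagens and matrix proteins, 6 rose, 8 fell and 10 did not pass, and the number of falls adjusted over the list alone was 7. Col1a1 was at 118454 ± 8173 and 117159 ± 10989 (adjusted p = 0.882), but was called lower under quantile normalization (log2 change -1.08, adjusted p = 1.17e-04) and library total scaling (-0.59, adjusted p = 0.00175). Tnc and Dcn rose 4.87-fold and 3.17-fold, and Lox, an enzyme that crosslinks collagen, fell 7.21-fold. Camera did not call the contractile list (adjusted p = 0.314) or the matrix list (adjusted p = 0.663), but called the matrix list lower under quantile normalization (median -0.85, adjusted p = 0.00998). Under both quantile normalization and library total scaling 4 matrix genes were higher and 18 lower, and of the contractile genes 2 were higher and 10 or 12 lower.

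Matrix proteases and their inhibitors split 8 higher, 7 lower and 4 not passing, 8 lower when adjusted over the list alone, and 7 higher and 11 lower under library total scaling. The inhibitor genes Timp1 and Timp3 rose 12.2-fold and 7.06-fold, and Mmp11 and Adamts1 fell 15.4-fold and 10.9-fold. The median of this list was -0.22 and its mean 0.56, and camera did not call it (adjusted p = 0.924). Among 20 inflammatory fibroblast genes, 11 rose, led by Saa3, Ccl2 and the hyaluronan synthase gene Has1 (36.9-fold), 7 fell, Cxcl12 among them, and 2 did not pass (camera adjusted p = 0.122); without the first or the second control library camera called the list higher (adjusted p = 0.0493 and 0.0383), as it did under quantile normalization (adjusted p = 0.0310) and library total scaling (adjusted p = 2.89e-04). TGF-beta responsive genes split 7 higher, 8 lower and 2 not passing, with Ltbp2 up 3.64-fold and Junb up 4.81-fold, a median of -0.06, a mean of 0.20 and a camera adjusted p of 0.924. Of 13 stellate cell markers, 5 rose, 6 fell and 2 did not pass: Pdgfra rose 1.82-fold and Nes 1.83-fold, while the lipid droplet gene Plin2 fell 2.10-fold and Fap 1.87-fold (camera adjusted p = 0.663). Pdgfra lost its call under quantile normalization (log2 change 0.12, adjusted p = 0.226), where 1 marker was higher and 9 lower, against 2 higher and 9 lower under library total scaling.

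Metabolic genes rose in part. All 17 glycolysis genes rose, by a median log2 change of 1.26, including Hk2 (41.8-fold) and the glucose transporter gene Slc2a1 (6.45-fold), with a camera adjusted p of 9.32e-07 and an adjusted p of 0.334 with an estimated correlation. Under quantile normalization 14 of the 17 rose and 2 fell, and under library total scaling 15 rose and 1 fell. Of 15 unfolded protein response genes, 12 rose and 3 did not pass; Atf3 rose 23.9-fold, the chaperone gene Hspa5 2.74-fold and Atf4 2.70-fold (camera adjusted p = 9.46e-04; adjusted p = 0.390 with an estimated correlation). Under library total scaling that list had 9 higher and 5 lower genes. Of 20 cholesterol biosynthesis genes, 4 rose and 10 fell, with Dhcr7 down 3.31-fold (camera adjusted p = 0.243); 0 rose and 11 fell under quantile normalization (median -0.51), and 0 rose and 13 fell under library total scaling (median -0.93), against a median of -0.36. All 20 of the cholesterol genes were lower in the second control library than in the first, and without that library camera called the list lower, with a median of -0.53 (adjusted p = 0.0383).

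Of 22 genes of the G2 and M phases, 16 fell, 6 did not pass and the number higher was 0, with a median log2 change of -0.25 (camera adjusted p = 9.07e-04; adjusted p = 0.390 with an estimated correlation); Kif20a and Bub1b, which act in mitosis, fell 1.75-fold and 1.65-fold. All 22 were lower under quantile normalization (median -0.72) and under library total scaling (median -0.82). Of 22 S phase genes, 15 rose and 3 fell, 16 and 3 when adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.0117; adjusted p = 0.390 with an estimated correlation), and this direction turned under quantile normalization (median -0.15, 5 higher and 11 lower) and library total scaling (median -0.22, 1 higher and 12 lower). Immediate early genes split 13 higher and 5 lower, 11 and 8 under library total scaling, with Klf6 up 5.32-fold and Zfp36 up 5.25-fold (camera adjusted p = 0.0607), and camera called the list higher without the first control or the first treated library (adjusted p = 0.0305 and 0.0338), without the filter (0.0212), under quantile normalization (0.0143) and under library total scaling (0.00121). Of 22 ribosomal protein genes, 11 rose and 1 fell, 9 and 1 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0507, and 0.0157 without the first treated library and 0.0151 without the filter); the median turned to -0.61 under quantile normalization, where camera called the list lower (adjusted p = 3.95e-05), and -0.40 under library total scaling. None of the 15 mitochondrially encoded genes of the list was in the deposited table under its symbol, so their level is not known.

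Markers of other cell types were mostly low or unmeasured. None of the 16 T, B and NK cell markers passed the filter. Of 6 measured myeloid markers only Fcgr3 was called, at 10.6 ± 0.842 and 121 ± 1.0 normalized counts, while Cd14 was at 354 ± 32.1 and 405 ± 9.06 and Lyz2 at 14.0 ± 0.674 and 8.13 ± 1.05 (camera adjusted p = 0.663 for the list). Cd14 was called higher under quantile normalization (log2 change 0.41) and lower under library total scaling (-0.37), and Lyz2 lower under the latter (-1.24). Mrc1 (log2 change 0.89, adjusted p = 0.0634) was called higher under quantile normalization (1.14, adjusted p = 0.0307) and without the first treated library (1.26, adjusted p = 0.0243). In all, 3 markers were higher under quantile normalization, and 1 was higher and 4 lower under library total scaling. Of 4 measured epithelial and acinar markers, 2 rose (Muc1 and Sox9) and 2 fell (Krt18 and Krt19), with Krt18 at 45.5 ± 1.12 and 3.57 ± 1.91 (camera adjusted p = 0.869); Sox9 lost its call under library total scaling (log2 change 0.11, adjusted p = 0.515). Of 10 endothelial and mural markers, 3 rose, 3 fell and 4 did not pass, 2 and 3 when adjusted over the list alone (camera adjusted p = 0.405), against 1 higher and 7 lower under library total scaling (median -0.99, against -0.44). The receptor gene Flt1 rose 41.1-fold, whereas the endothelial genes Vwf and Emcn fell 5.76-fold and 4.56-fold.

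In all, camera called 18 of the 30 lists tested, 17 higher and 1 lower. With a correlation estimated from these 4 libraries it called 0, with 3 lists at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 24 in 1 direction. The counts of members adjusted over the list alone equalled those over all genes, apart from the lists where both are given.

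**Figure D3:**
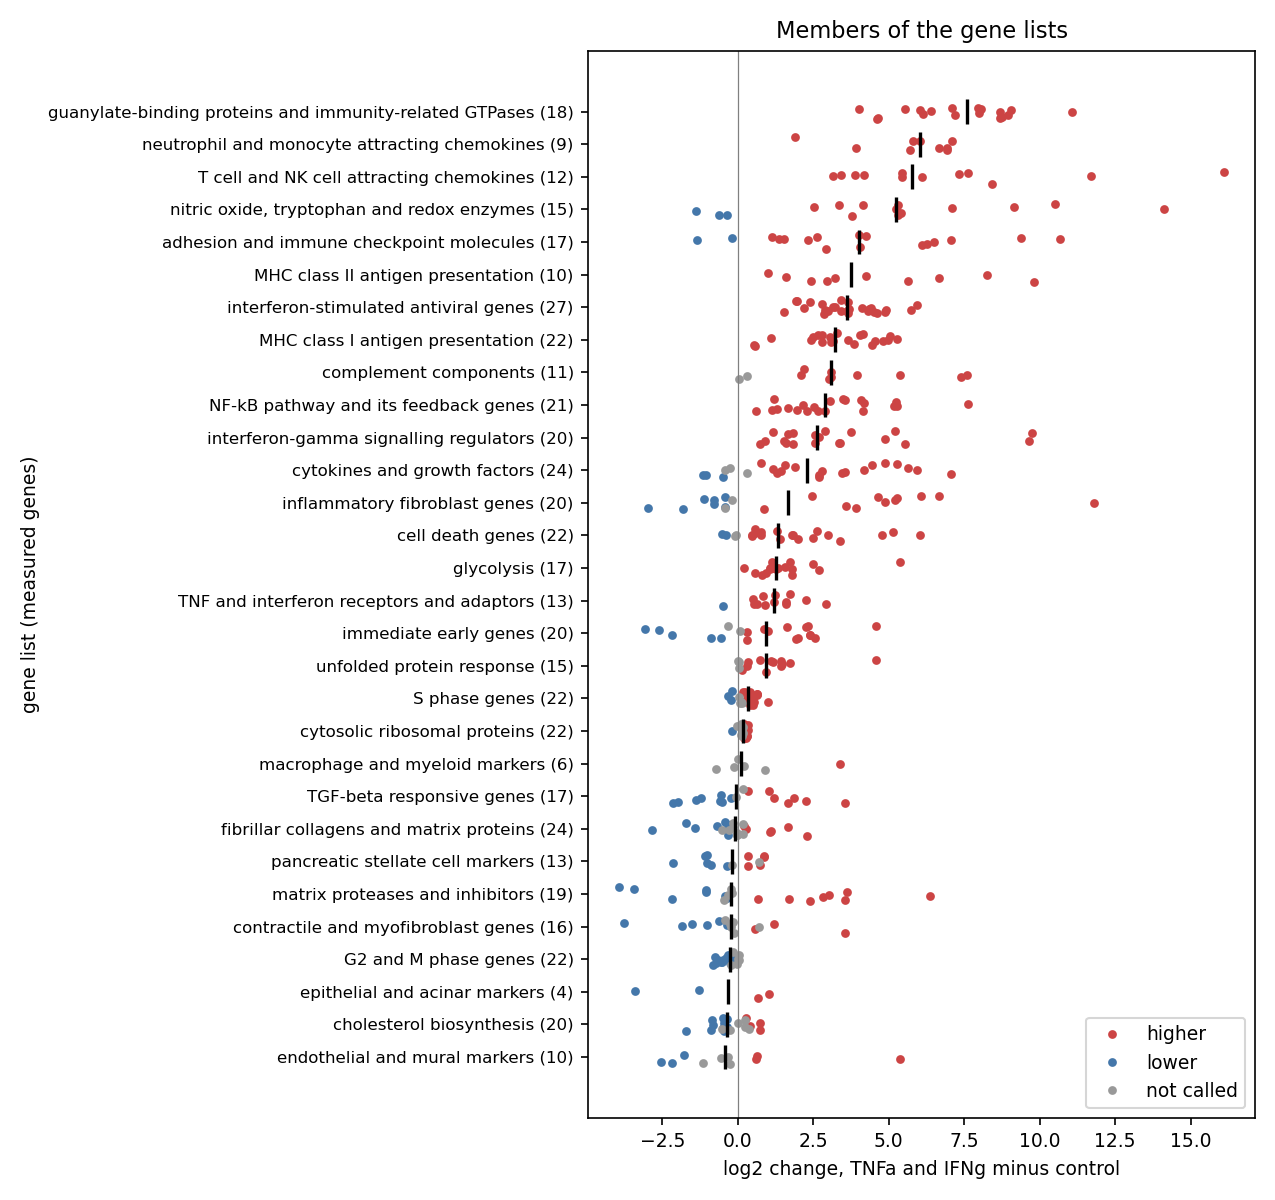
Log2 change, treated minus control, of every measured member of the 30 tested gene lists; each point is a gene coloured by its limma call, the vertical bars are list medians, and the number of measured genes stands in brackets. Medians run from 7.59 for the guanylate-binding proteins and immunity-related GTPases to -0.44 for the endothelial and mural markers.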

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

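Scaling by the library total, TMM factors for lists, chemokines and named genes, median centring for lists and a pairing by column order were added after the data were seen. The count of changed genes stayed between 9475 and 11678 under every alternative except the 2-fold minimum, which left 4401 because it is stricter; edgeR called 10667 genes and DESeq2 9890 on the recovered reads. With 1 library left out, the lone library being assumed to vary like the other group, 9475 to 10035 genes were called; without a control library the prior df rose from 3.75 to 7.0 or 6.93, which lowers p, so calls gained there are weak evidence. Chemokine calls numbered 26 or 27 under every alternative in which they were counted, which leaves out the filter of 50 and limma without a trend. Camera with an estimated correlation called 0 lists, and with 4 libraries that estimate is imprecise. A larger correlation cannot be the cause for every list. The glycolysis, adhesion, cell death and nitric oxide lists had estimates of -0.0072, -0.026, 0.0047 and 0.0077, under the preset 0.01. All 4 still had an adjusted p of 0.334 in that form of camera. It works with the 2 residual df of these libraries, which leaves it little power, so its adjusted p are no evidence against a list. The other called lists had estimates above 0.01, up to 0.80 for the antiviral, 0.49 for the complement and 0.48 for the neutrophil and monocyte chemokine list. For those lists the preset may be too low, so their camera adjusted p at 0.01 may be too small. The lower of the 2 correlations within a group was 0.996 at a mean of at least 50. No paired analysis was possible because the value columns carry no replicate number, so the planned replicate block was not run. This limit holds for pairs taken from the labels, while the paired fit given below assumes that columns pair by their order. Differences between the libraries of a group correlated across groups in column order (Pearson r of 0.304 over 11591 genes with a mean of at least 100), so the columns may be paired, which no label states. Pairing by column order, with 1 residual df, called 11183 genes and 19 lists; it called Acta2 higher (log2 change 0.71, adjusted p = 1.19e-05) and the ribosomal list higher (adjusted p = 0.0258) and changed no other call of a named gene or list, so the unpaired Acta2 value leaves its rise open. Of 150 named genes, 136 kept direction and call under every alternative run on them, but most were chosen for large changes or a small adjusted p, which favours stability. Of the 10602 called genes, 815 changed sign under quantile normalization and 2000 under library total scaling. Under the latter, 20 of 21 NF-kB, 26 of 27 antiviral and 19 of 20 IFNg signalling genes were called higher. For MHC class I and class II the numbers were 20 of 22 and 9 of 10, and no gene of these lists was called lower. Among the genes and lists reported here, the sign turned, for causes not tested, for these: without 1 library, Col1a1 (log2 change from -0.113 to 0.0785) and the myeloid list (median from -0.0156 to 0.229); under quantile normalization, Rpl37 (-0.39), Rps19 (-0.45) and the list medians of TGF-beta responsive genes (0.0114), S phase genes (-0.15) and ribosomal proteins (-0.61); under library total scaling, Rpl27 (-0.23), Rpl37 (-0.26), Rps19 (-0.36), Cd14 (-0.37), S phase genes (-0.22), ribosomal proteins (-0.40) and myeloid markers (-0.46). Depth limits the fold of genes with a few reads in a group, such as Ubd.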

Other observations

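The gene families in this part were chosen after their values were seen and adjusted over the 11 families tested, and every test of an explanation was chosen after its pattern was seen. Interleukin receptor genes rose along with the cytokines, with 20 of 24 measured genes higher and 2 lower, and 16 higher and 3 lower under library total scaling (camera adjusted p = 8.19e-05; adjusted p = 0.160 with an estimated correlation). Il1rl1, the receptor for interleukin 33, went from 1910 ± 489 to 105223 ± 26096 normalized counts (SD, n = 2), and Il15ra and Il13ra1 rose 100.5-fold and 8.82-fold. All 7 Schlafen genes rose by a median log2 change of 6.51 (camera adjusted p = 5.48e-04; adjusted p = 0.183 with an estimated correlation), and all 10 interferon-inducible genes of the p200 family rose by a median of 6.30 (camera adjusted p = 1.38e-04; adjusted p = 0.369 with an estimated correlation). The Schlafen median is the value of Slfn1, which had no control read, so its size depends on the pseudocount. Slfn4 and Slfn3 had 1 and 2 control reads. All 31 constitutive proteasome subunit genes rose, by a median of 0.73 (camera adjusted p = 3.60e-08; adjusted p = 0.160 with an estimated correlation), though 23 rose and 3 fell under quantile normalization and 16 rose and 5 fell under library total scaling. Camera did not call the iron genes (adjusted p = 0.0631), of which 6 rose and 3 fell: the iron exporter gene Slc40a1 fell 43.3-fold, resting on 13 treated reads, while the metalloreductase gene Steap4 rose 145-fold, the transferrin receptor gene Tfrc 3.05-fold and the ferritin gene Fth1 2.15-fold.

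Of 12 Hedgehog pathway genes 9 fell and 1 rose (camera adjusted p = 0.00261; adjusted p = 0.266 with an estimated correlation), with the coreceptor gene Gas1 going from 17204 ± 1352 to 1256 ± 348 normalized counts, Gli2 falling 3.23-fold and Ptch1 3.09-fold. Camera did not call the 14 genes of nitric oxide and cyclic GMP signalling (adjusted p = 0.142), of which 8 fell and 5 rose: the guanylate cyclase gene Gucy1a2 fell 4.52-fold and Gucy1b1 went from 57.6 ± 32.6 to 4.74 ± 2.0 normalized counts, and of the phosphodiesterase genes Pde5a fell 11.2-fold and Pde1a rose 2.92-fold. Camera did not call the 15 circadian clock genes either (adjusted p = 0.105), of which 10 fell and 4 rose, with the clock output genes Dbp and Tef down 8.30-fold and 2.90-fold.

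Of 32 Hox genes, 27 fell and 2 rose (25 and 2 under quantile normalization, 29 and 0 under library total scaling), with a median log2 change of -1.40 (camera adjusted p = 1.24e-06; adjusted p = 0.160 with an estimated correlation), of 319 Zfp-named zinc finger genes 186 fell and 51 rose (177 and 42 under quantile normalization, 279 and 15 under library total scaling; median -0.41, camera adjusted p = 1.37e-05; adjusted p = 0.408 with an estimated correlation), and of 41 protocadherins 31 fell and 4 rose (20 and 2, and 38 and 2, under these scalings; median -0.75, camera adjusted p = 5.48e-04; adjusted p = 0.318 with an estimated correlation). Weakly expressed genes fell in general, by a median of -0.49 at means of 10 to 100 and -0.32 at 100 to 1000, against 0.21 at 1000 or more. Each family median was therefore set against the medians of 10000 random lists matched on mean expression. The middle 95% of those medians reached down to -0.81 for the Hox genes and -0.29 for the zinc finger genes, above both observed medians, but to -0.75 for the protocadherins, whose median lay just inside that range and whose fall may be part of the general one. Of the scalings only quantile normalization can test this, since the others shift all genes alike: relative to all genes it took the medians from -1.41 to -1.13 for Hox, -0.42 to -0.21 for zinc finger and -0.76 to -0.38 for protocadherin genes, and medians of -1.26, -0.35 and -0.51 stood against matched lists reaching down to -0.61, -0.25 and -0.59. The size of the fall thus depends on the scaling, while for the Hox and zinc finger genes it stayed beyond that of matched genes. These families were chosen after their values were seen. Random lists allow neither for that choice nor for family members that vary together, so the comparison describes these libraries and is no independent test. GC content and transcript length were not checked and stay open.

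The second control library had more interferon-stimulated transcripts than the first: Ifit3 stood at 2046 and 7741 normalized counts, Mx1 at 61.5 and 210.6, Irf7 at 1288 and 3231, and the median log2 difference of the 27 antiviral genes was 1.12. Carry-over of treated material would need 7.20% of the treated level, but the 10 most raised genes reached at most 0.140% there, with Cxcl9 at 9.58 and 14.5. The median difference over all genes with a mean of at least 100 was -0.0108. The size factors align the typical gene between libraries, so this median alone cannot test a difference in depth or scaling. It shows only that the antiviral genes stood apart from other genes, which a factor common to all genes would not produce. A trace of both cytokines would be expected to raise NF-kB genes too, whose median difference was 0.0621. Chemokines that attract neutrophils and monocytes, however, were higher in that library for 8 of 9 genes, by a median log2 difference of 0.38. Among these 8, Ccl12 and Cxcl3 had only 1 and 10 control reads. A trace of both cytokines is thus not excluded. Interferon signalling without an NF-kB response in that culture is a hypothesis that these samples cannot test.

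The treated libraries summed to 1.48 times the normalized counts of the controls. A few abundant transcripts are not enough to account for this, since the ratio was still 1.30 without the 50 genes with the largest rise, which held 39.4% of the added counts. More RNA per cell could give the same ratio of 1.48, as could a size factor set by genes that fell, and these cannot be told apart without an external RNA standard or cell counts. The direction of small changes, as in ribosomal protein and S phase genes, therefore stays open.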
